A study of Homo sapiens with 4 samples.

How the data were processed

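Gene expression was measured on Affymetrix whole-transcript arrays in HCT116 cells, an established human colon cancer line. Per the labels' protocols, the cells were transiently transfected with plasmids that express PRSS8 or with the vector control, and total RNA was extracted with Trizol and biotin-labelled. There were 4 arrays, 2 of the control and 2 of PRSS8 overexpression. The labels number the replicates 1 and 2 in each group and call them biological; the time between transfection and collection is not given in the sources used here.

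The deposited values are log2 expression levels per probe set. They were made with Affymetrix Expression Console 1.3.1 and RMA (background correction, normalization between arrays and summary of the probes), per the submitters' processing notes. Whether the 4 arrays were normalized together is not given in the sources used here, and the deposited columns did not share one distribution. No scanner files were available, so background and detection could not be computed, and the number of arrays limits the precision.

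The table held 70523 probe sets. Of these, 2995 control and exon-level probe sets were left out of the tests, which left 67528 transcript clusters (gene-level probe sets). GEO's annotation of the platform listed 25324 probe sets, 23781 with 1 gene symbol and 1543 with several; the other 42204 transcript clusters had no entry and are unnamed here, which does not mean that they lack a gene. Symbols were updated through the Entrez identifier for 21497 probe sets (90.4%) and through a unique older symbol for 306. Where a gene had more than 1 probe set (528 genes), the one with the highest mean over the 4 arrays stood for it, which gave 22411 genes. No filter on dim probe sets was applied, and no coordinates are given because the sources used here do not name the genome build of the annotation.

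PRSS8 overexpression was compared with control in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment over all genes, with an adjusted p under 0.05 as the threshold. This fit had 2 residual degrees of freedom per gene before moderation. Differences are PRSS8 overexpression minus control on the log2 scale with the moderated standard error (SE), and levels are means with the standard deviation (SD) of 2 arrays. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333. For that reason a count with no test was also made, of genes whose lowest level in one group exceeded the highest in the other by at least 1.5-fold.

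The design, the alternatives, 34 gene lists and 5 lists of markers of other cells were fixed before the data were examined. Of the lists' genes, those matched by symbol to the 22411 genes were tested, in lists of at least 5 members. Lists were tested with limma's camera at the preset correlation of 0.01, adjusted over the 34 lists, and beside it with an estimated correlation and with fry. With an estimated correlation camera uses the residual degrees of freedom, 2 here, which leaves it little power. Genes were named by a rule fixed in advance. It took PRSS8, the 10 largest differences in each direction, and up to 4 members per list, together with SPHK1, CDH1, VIM, STAT3 and AKT1. The largest differences were taken among genes past the threshold whose 4 array-to-array differences had one sign and whose mean in at least one group lay above the median of all genes. As no gene passed, those places were filled with the largest differences that met the other conditions and with the 2 members of smallest p in each list. Other members of the lists, and genes with groups at least 1.5-fold apart, were chosen after their values were seen.

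Because the arrays also differed by replicate number, differences are given within each number as well. The main fit had no block for the number, so its SEs and p-values include the difference between the numbers. Pair 1 is the overexpression array of replicate 1 minus the control array of replicate 1, and pair 2 is the same for replicate 2. List medians were set against 10000 random lists of the same size matched on mean level. The alternatives were other variance models, limma's treat, the unmoderated test, the replicate number as a block, filters on dim probe sets, 3 further normalizations (quantile, median centring and cyclic loess), the mean of a gene's probe sets, every transcript cluster as its own entry, other fold sizes and leaving out each array. Leaving out an array left 1 array in its group, which was assumed to vary like the 2 of the other group. The groups then also differ in replicate number, so these differences carry part of the difference between the numbers. Chosen after seeing the data were 6 further gene lists, the set tests that combine the block with an estimated correlation or with fry, and the counts of genes 1.5-fold apart within both pairs.

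The code was tested on simulated data for PRSS8 overexpression minus control over the 22411 genes, with 50 genes changed at each size. The fit without a block called 0 of 50 at a log2 change of 1, 19 of 50 at 2, 36 of 50 at 4 and 38 of 50 at 7, with 0 unchanged genes called. With the replicate block, 32, 45, 50 and 50 of 50 were called, with 9 unchanged genes called. All sizes were planted in the same simulated arrays, and Benjamini-Hochberg adjustment is easier to pass when many genes change. The counts therefore do not give the power to call a single changed gene. On the real arrays PRSS8 differed by 7.49 and was not called.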

Results

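The data are 4 arrays of HCT116 cells, 2 after transfection with a PRSS8 plasmid and 2 after transfection with the vector control. PRSS8 encodes prostasin, a serine protease anchored in the membrane of epithelial cells. The median level over transcript clusters was 3.60 and 3.92 on the control arrays (replicates 1 and 2) and 3.61 and 3.86 on the PRSS8 arrays. Values reached an upper limit of 19.93 on both replicate 1 arrays and of 19.44 (control) and 19.46 (PRSS8) on the replicate 2 arrays, and 5 to 15 genes per array stood at it, none of them named here. Arrays of the same number were closest to each other: across genes, Pearson's r was 0.996 between the replicate 1 arrays and 0.989 between the replicate 2 arrays, but 0.930 between the 2 control arrays and 0.934 between the 2 PRSS8 arrays.

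The comparison asks which transcripts differ when HCT116 cells are made to express PRSS8. PRSS8 itself (probe set TC16001050.hg.1) stood at 10.82 ± 0.52 on the control arrays and at 18.31 ± 0.34 on the PRSS8 arrays (log2, SD, n = 2 each), a difference of 7.49 (SE 0.57), or 180.3-fold. Genes of the unfolded protein response, the program by which cells raise the folding capacity of the endoplasmic reticulum (ER) had a median difference of 0.81 as a list (camera, adjusted p = 6.0e-22; adjusted p = 0.63 with an estimated correlation). In that list HERPUD1, a component of ER-associated degradation, stood at 12.14 ± 0.16 against 8.54 ± 0.26 (12.1-fold), and 20 of the 21 measured genes of that list were higher in both pairs of arrays. Genes of the integrated stress response, headed by the transcription factor DDIT3 (CHOP), were higher in both pairs for 16 of 25 members. Among genes whose 4 array-to-array differences had one sign, the largest negative differences were those of microRNA genes of the MIR548 family, ABCC2 and CYP24A1.

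No single gene passed the threshold. In limma, 0 of 22411 genes were higher and 0 lower at an adjusted p under 0.05, where 42 genes had an unadjusted p under 0.05 (17 higher, 25 lower). PRSS8 had an adjusted p of 1, as did every other gene after rounding. PRSS8 differed by 7.13 without control replicate 1 and by 7.86 without control replicate 2. Fits with an array left out also carry part of the difference between the replicate numbers. The differences of PRSS8 were 8.10 in pair 1 and 6.89 in pair 2.

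In 16 genes both PRSS8 arrays stood at least 1.5-fold above both control arrays, and in 8 genes at least 1.5-fold below. When each control array was instead grouped with the PRSS8 array of the other number, these counts were 0 and 1, and grouping the arrays by number gave 2938 and 864. Without a fold limit, 5.53% of genes had both PRSS8 arrays above both controls and 5.56% below, where chance would give 16.7% each way if the 4 arrays were exchangeable. They were not, as arrays of one number moved together, and the grouping across numbers gave 4.44% and 5.07%. All 16 higher genes were protein coding. Besides PRSS8, 5 belonged to the unfolded protein response list (HERPUD1, HYOU1, PDIA4, MANF and SEC61B), 3 to the integrated stress response list (DDIT3, WARS1 and AARS1), and 3 to other lists (WIPI1, NDRG1 and PLAUR). The other 4 were DERL2, a part of the machinery that returns misfolded ER proteins to the cytosol (difference 1.48, SE 0.76), the carboxypeptidase CPA4 (1.40, SE 0.38), FBXO16 (1.08, SE 0.45) and ARF4, a small GTPase of Golgi transport (0.85, SE 0.59). The 8 lower genes were MIR548AI, MIR548AJ2, MIR548F1, MIR548Q, MIR590, MIR4786, the immunoglobulin segment IGHJ1 and the pseudogene RNU7-28P.

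**Figure D1:**
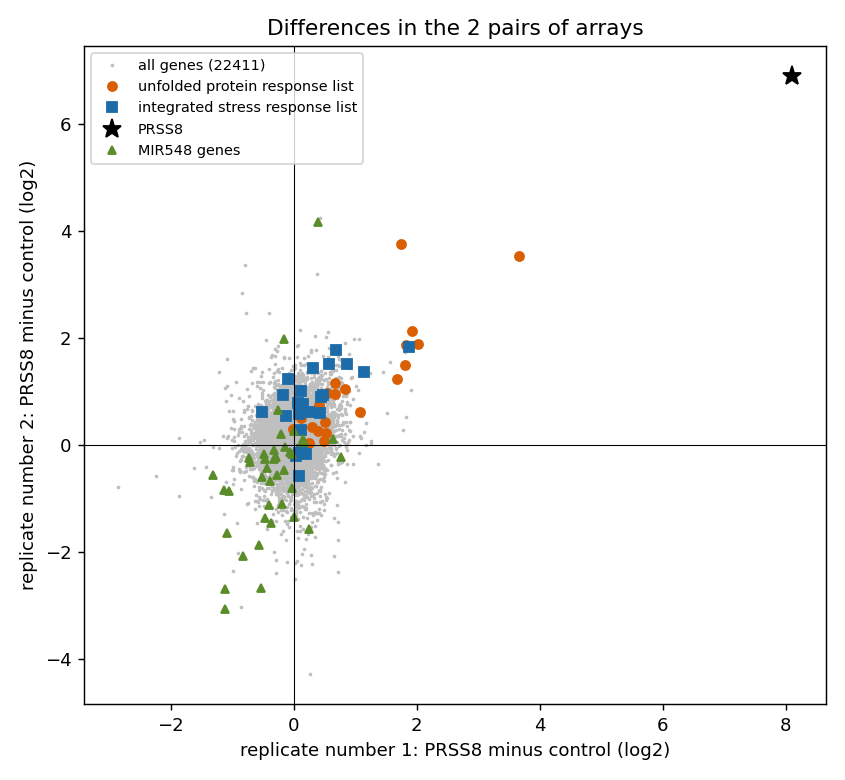
Difference between the PRSS8 array and the control array (log2) of replicate 1 on the horizontal axis and of replicate 2 on the vertical axis, one point per gene, with PRSS8, 2 stress lists and MIR548 genes marked. PRSS8 lies at 8.10 and 6.89, and the unfolded protein response genes lie mostly in the upper right.

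The unfolded protein response list was shifted up (camera, adjusted p = 6.0e-22, median difference 0.81, 21 members). The call was lost with an estimated correlation (adjusted p = 0.63), with fry (adjusted p = 0.92) and without control replicate 2 (adjusted p = 0.093), in a range of 2.9e-24 to 0.92 over 15 alternatives. Without PRSS8 replicate 1 the median was 0.37. On all arrays it was 0.67 in pair 1 and 0.94 in pair 2, and in 13 of the 21 genes both PRSS8 arrays stood above both controls. Higher in both pairs were 20 members, or all but the stress sensor ERN1, whose differences were −0.02 and 0.29; among all genes 26.0% were higher in both pairs, and 38.0% among genes with a mean level of at least 6. The ER chaperone HSPA5 (BiP) differed by 2.75 (SE 1.24), with 1.74 in pair 1 and 3.75 in pair 2. HYOU1, another ER chaperone, differed by 1.94 (SE 0.80), the disulfide isomerase PDIA4 by 1.84 (SE 0.91) and the co-chaperone DNAJC3 by 2.02 (SE 1.80). SEL1L, the scaffold of the ER ubiquitin ligase, differed by 1.65 (SE 1.67), and XBP1, a transcription factor of this response, by 0.81 (SE 0.53). In either direction, fry's mixed test gave the list an adjusted p of 0.0016. Counted at an adjusted p under 0.05, 0 members passed over all genes and 0 adjusted over the list alone.

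**Figure D2:**
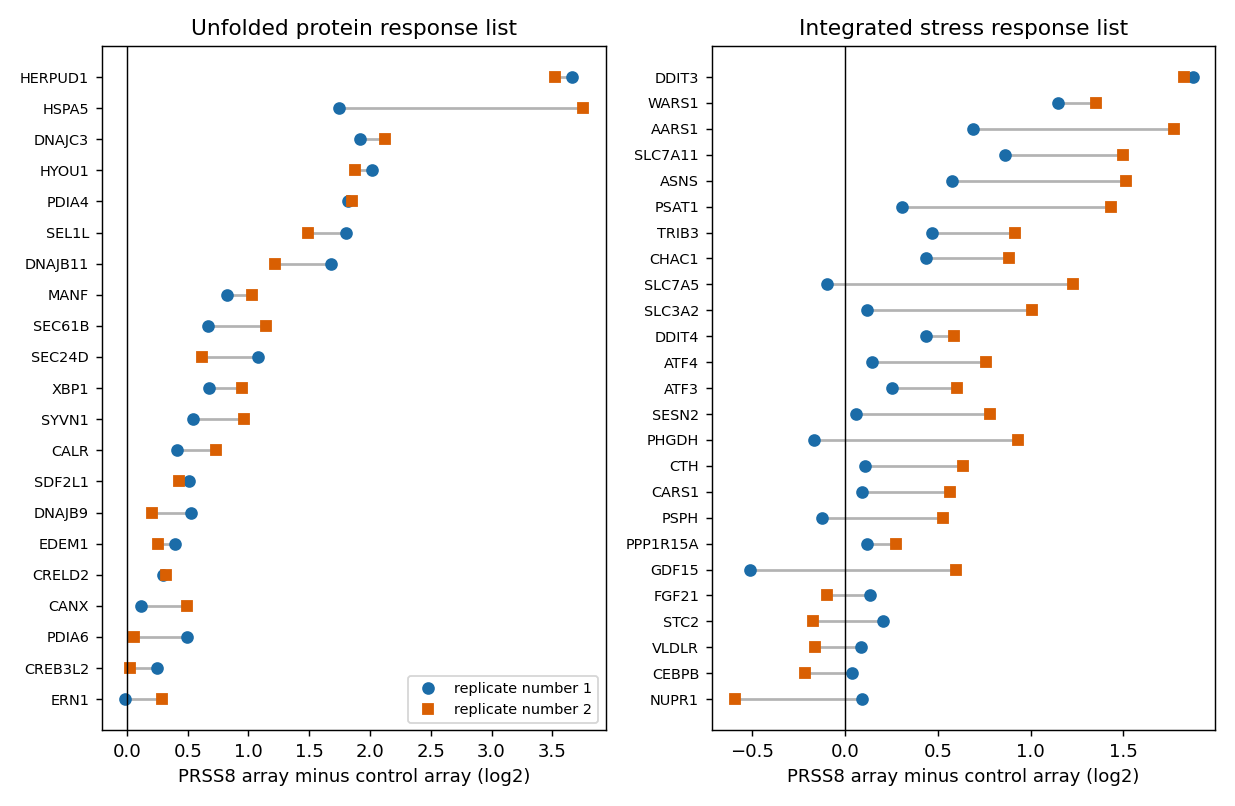
Difference between the PRSS8 array and the control array (log2) for each member of the unfolded protein response list and the integrated stress response list, with circles for replicate 1 and squares for replicate 2. Of the first list 20 of 21 genes lie above 0 in both pairs, and of the second 16 of 25.

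The integrated stress response list, genes induced by the transcription factor ATF4, was shifted up as well (camera, adjusted p = 2.0e-09, median difference 0.43). That call was lost with an estimated correlation (adjusted p = 0.63), with fry (adjusted p = 0.92) and without control replicate 2 (adjusted p = 0.16), in a range of 1.6e-11 to 0.92 over 15 alternatives. The median was 0.25 without PRSS8 replicate 2 and 0.27 without control replicate 2. On all arrays it was 0.13 in pair 1 and 0.76 in pair 2, and 19 of 25 members differed more in pair 2 than in pair 1. DDIT3 stood at 8.02 ± 0.32 against 6.17 ± 0.29, a difference of 1.85 (SE 0.48), with 1.87 in pair 1 and 1.83 in pair 2. The tRNA synthetases WARS1 and AARS1 differed by 1.25 (SE 0.58) and 1.23 (SE 0.68), the cystine transporter SLC7A11 by 1.18 (SE 2.20) and asparagine synthetase (ASNS) by 1.05 (SE 0.63). ATF4 differed by 0.45 (SE 0.74), while NUPR1 differed by −0.25 (SE 0.37) and CEBPB by −0.09 (SE 0.22).

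The proteasome list was shifted up (camera, adjusted p = 9.5e-05, median difference 0.49; adjusted p = 0.63 with an estimated correlation), with 19 of 24 subunits higher in both pairs. Its median was 0.16 in pair 1 and 0.78 in pair 2, and all 24 subunits differed more in pair 2. PSMB3 differed by 1.19 (SE 1.04) and PSMA1 by 0.79 (SE 0.72). The call was also lost with fry (adjusted p = 0.92) and after quantile normalization (median 0.32, camera, adjusted p = 0.20), in a range of 1.4e-08 to 0.92 over 15 alternatives. It was lost too without PRSS8 replicate 1, where the median stayed at 0.49, and without control replicate 2. The median was 0.24 without PRSS8 replicate 2 and 0.24 without control replicate 2, where camera's direction was down.

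The other 5 lists that passed had smaller shifts, and each lost its call with an estimated correlation, with fry, under all 3 further normalizations and without control replicate 2. Median centring moved the difference of every gene by the same amount, and the median over all genes went from 0.0006 to 0.032. The medians of the 5 lists (0.15 to 0.31) rose with it, so their shift against other genes was unchanged and that lost call was not a smaller shift. They were smaller after cyclic loess (0.09 to 0.24) and after quantile normalization (0.08 to 0.19), where oxidative phosphorylation went from 0.20 to 0.09. Mitotic genes had a median of 0.28 (camera, adjusted p = 0.021; adjusted p = 0.63 with an estimated correlation) and were higher in both pairs for 24 of 29 members, with PLK1 at 0.70 (SE 0.88) and CDK1 at 0.50 (SE 0.66). Leaving out an array turned or multiplied that median: it was −0.15 without PRSS8 replicate 1, −0.09 without control replicate 2, 1.09 without control replicate 1 and 1.29 without PRSS8 replicate 2. Genes of oxidative phosphorylation had a median of 0.20 (adjusted p = 0.017; adjusted p = 0.70 with an estimated correlation), but −0.02 in pair 1 and 0.40 in pair 2, with NDUFB5 at 0.53 (SE 0.45) and UQCRB at 0.24 (SE 0.21). That median was −0.08 without PRSS8 replicate 2, 0.11 without control replicate 1 and 0.36 without PRSS8 replicate 1. Epithelial junction genes had a median of 0.19 (adjusted p = 0.021; adjusted p = 0.63 with an estimated correlation), 0.06 in pair 1 and 0.42 in pair 2, and 0.04 without PRSS8 replicate 2 and 0.34 without control replicate 1. In that list the claudin gene CLDN4 differed by 0.71 (SE 0.63), the epithelial factor OVOL1 by 0.36 (SE 0.32) and E-cadherin (CDH1) by 0.18 (SE 0.82). Oxidative stress genes had a median of 0.18 (adjusted p = 0.021; adjusted p = 0.63 with an estimated correlation), with GCLM at 0.51 (SE 0.52) and AKR1C1 at 0.17 (SE 0.16), and a median of 0.03 without PRSS8 replicate 2 and 0.11 without control replicate 2. Hypoxia and glycolysis genes had a median of 0.12 (adjusted p = 0.023; adjusted p = 0.63 with an estimated correlation), 0.20 in pair 1 and 0.03 in pair 2, with NDRG1 at 0.83 (SE 0.62) and ANKRD37 at 0.28 (SE 0.19). Its median was 0.01 without PRSS8 replicate 1, 0.07 without control replicate 2, 0.19 without control replicate 1 and 0.24 without PRSS8 replicate 2, with camera's direction down in the first 2 of these. Of the 5 calls, those of mitotic and oxidative stress genes held without control replicate 1, those of mitotic and hypoxia genes without PRSS8 replicate 2, and none without PRSS8 replicate 1.

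**Figure D3:**
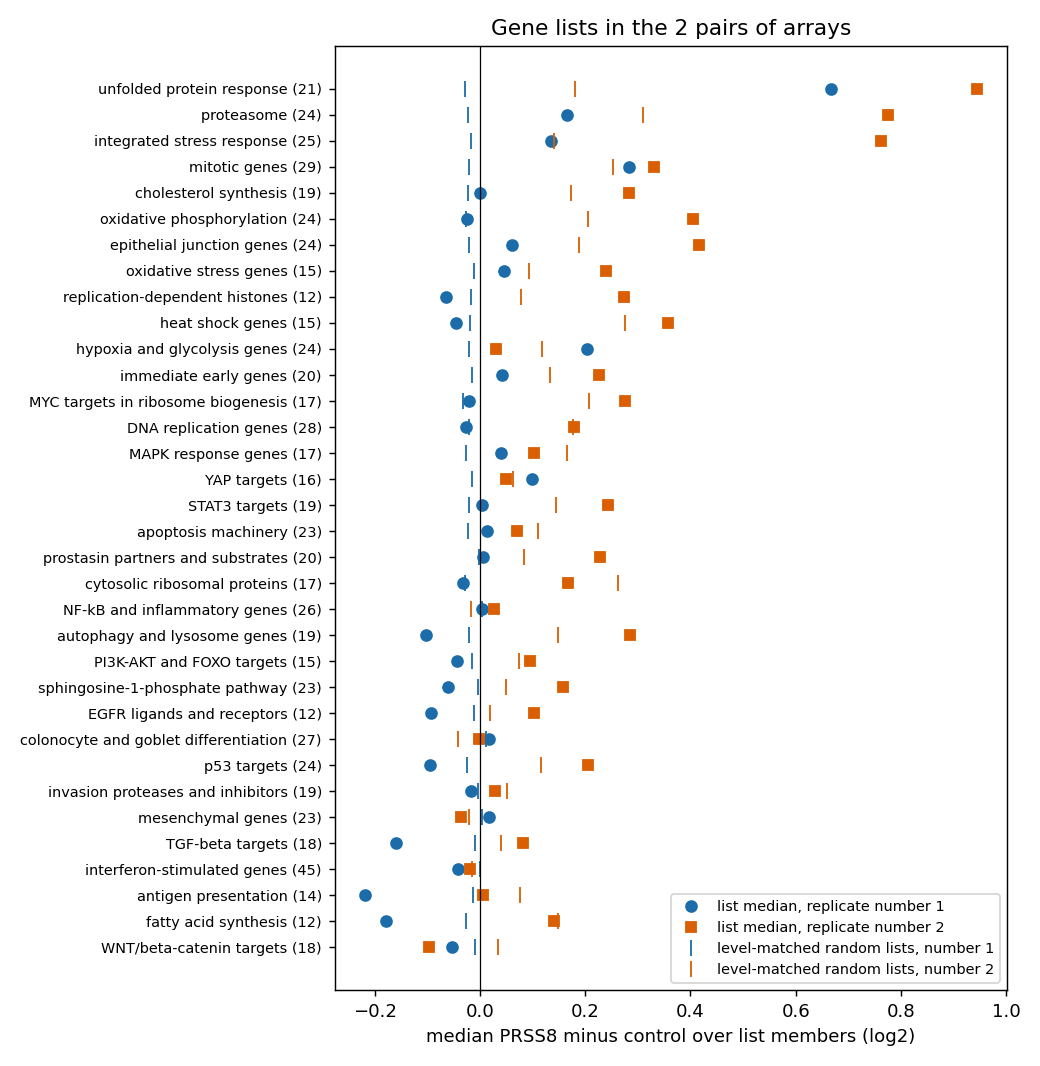
Median difference between the PRSS8 array and the control array (log2) over the members of each of the 34 gene lists, with circles for replicate 1, squares for replicate 2 and ticks for the median of random lists matched on level; numbers of members are in brackets. The unfolded protein response list lies farthest from 0, at 0.67 and 0.94.

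The other 26 lists did not pass, with medians from −0.05 to 0.25 and camera adjusted p from 0.12 to 0.97. For 23 of the 26 the median took either sign depending on which array was left out, but such fits carry part of the difference between the replicate numbers. In all 34 lists 0 members passed over all genes and 0 adjusted over the list alone. For 4 of the lists the median, the mean and the camera direction did not share one sign: sphingosine-1-phosphate, EGFR, mesenchymal and colonocyte genes. Medians crossed 0 under at least 1 of the 3 further normalizations for p53 targets, DNA replication, ribosomal protein, interferon, mesenchymal, EGFR, invasion and autophagy genes.

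The lists of sphingosine-1-phosphate genes, STAT3 targets, AKT and FOXO genes, prostasin partners and mesenchymal genes did not pass. The epithelial junction list, described above, passed camera at the preset correlation but not with an estimated one. In the sphingosine-1-phosphate list (median 0.01, adjusted p = 0.95), the kinase gene SPHK1 stood at 3.75 ± 0.06 against 3.76 ± 0.09, near the median of all transcript clusters. Receptors S1PR4 and S1PR5 differed by −0.23 (SE 0.12) and −0.20 (SE 0.16). STAT3 targets had a median of 0.07 (adjusted p = 0.29), with FOSL1 at 0.81 (SE 0.65), TIMP1 at 0.46 (SE 0.51) and STAT3 itself at −0.27 (SE 0.71). Among AKT and FOXO genes (median 0.01, adjusted p = 0.95), AKT1 differed by −0.15 (SE 0.63), INSR by −0.29 (SE 0.27) and GADD45A by 0.62 (SE 0.94). Prostasin partners and substrates had a median of 0.06 (adjusted p = 0.26), with TMPRSS13, a related membrane protease, at 0.15 (SE 0.16). Mesenchymal genes had a median of −0.02 (adjusted p = 0.75), with vimentin (VIM) at 3.76 ± 0.11 against 3.75 ± 0.08, SNAI1 at a difference of 0.38 (SE 0.44) and SPARC at −0.13 (SE 0.15). The median level of this list was 3.84, also near the median of all transcript clusters. As detection could not be computed, its small median difference does not show that these genes were unchanged.

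WNT/beta-catenin targets had a median of −0.05 (adjusted p = 0.12) and were lower in both pairs for 10 of 18 members, and they passed downward with genes below the median level left out (median −0.13, adjusted p = 0.022; on all genes adjusted p = 0.63 with an estimated correlation). SOX4, a transcription factor of intestinal progenitors, differed by −1.42 (SE 1.02), with −1.87 in pair 1 and −0.97 in pair 2, and AXIN2 by −0.23 (SE 0.17). Invasion proteases and their inhibitors had a median of 0.00 (adjusted p = 0.49), yet the urokinase receptor PLAUR differed by 1.25 (SE 0.56) and urokinase (PLAU) by 0.47 (SE 0.39). MAPK response genes had a median of 0.08 (adjusted p = 0.49), with the phosphatase DUSP5 at 1.01 (SE 0.66) and SPRY2 at −0.22 (SE 0.17). Medians were 0.10 for immediate early genes (adjusted p = 0.22), with IER2 at 0.39 (SE 0.40) and ATF3 at 0.43 (SE 0.47), and 0.01 for EGFR ligands and receptors (adjusted p = 0.74), with ERRFI1 at 0.95 (SE 0.94) and ERBB4 at −0.13 (SE 0.14). With an array left out, the median of immediate early genes was lower, at 0.016 to 0.067. TGF-beta targets had a median of −0.03 (adjusted p = 0.59) and YAP targets of 0.08 (adjusted p = 0.27). In these lists BHLHE40 differed by 0.62 (SE 0.54), TGFB2 by −0.18 (SE 0.15) and NUAK2 by 0.32 (SE 0.23). Colonocyte and goblet genes, at a low median level of 3.49, had a median of 0.01 (adjusted p = 0.97), with GUCA2B at 0.18 (SE 0.13) and ATOH1 at −0.17 (SE 0.14).

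Lists of responses to foreign DNA and damage showed no shift past the threshold on the 4 arrays. Interferon-stimulated genes had a median of −0.04 (adjusted p = 0.49) over 45 members, with OASL at 0.54 (SE 0.43) and IFNB1 at 0.26 (SE 0.18). The median level of this list was 3.88, near the median of all transcript clusters. Without detection values, a small median difference at that level does not show that the genes were unchanged. Antigen presentation genes had a median of −0.04 (adjusted p = 0.49), −0.22 in pair 1 and 0.01 in pair 2, with TAPBP at −0.30 (SE 0.50) and TAP2 at −0.16 (SE 0.32). For NF-kB and inflammatory genes, at a similarly low median level of 3.86, the median was 0.02 (adjusted p = 0.51), with CXCL8 at 0.35 (SE 0.22) and LTB at −0.16 (SE 0.12). For p53 targets it was 0.01 (adjusted p = 0.95), with PLK3 at 0.53 (SE 0.46) and CMBL at −0.19 (SE 0.16). Heat shock genes had a median of 0.16 (adjusted p = 0.49), with HSPA1A at −0.34 (SE 0.53) and HSPA6 at 0.16 (SE 0.18). That list passed upward without control replicate 1 (median 0.25, adjusted p = 0.036) and without PRSS8 replicate 2 (median 0.27, adjusted p = 0.010), while on the 4 arrays it had an adjusted p = 0.89 with an estimated correlation. Its median was −0.23 without PRSS8 replicate 1, −0.24 without control replicate 2 and 0.037 after quantile normalization. Apoptosis genes had a median of 0.06 (adjusted p = 0.20), with PMAIP1 (NOXA) at 1.15 (SE 1.25) and FADD at 0.42 (SE 0.38). Autophagy and lysosome genes had a median of 0.01 (adjusted p = 0.30), in which WIPI1, a protein of autophagosome formation, stood at 9.59 ± 0.03 against 8.05 ± 0.02 (difference 1.55, SE 0.64) and MAP1LC3B differed by 0.60 (SE 0.68).

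Among lists of growth and metabolism, cholesterol synthesis had a median of 0.25 (adjusted p = 0.16), 0.00 in pair 1 and 0.28 in pair 2, with HMGCS1 at 1.16 (SE 1.17) and HSD17B7 at 0.28 (SE 0.35). It passed upward with the replicate block (camera, adjusted p = 0.017), but not with the block and an estimated correlation (adjusted p = 0.88). Without a block it had an adjusted p = 0.63 with an estimated correlation. Its median was 0.12 after quantile normalization. With an array left out it was 0.28 without control replicate 1, −0.10 without control replicate 2, −0.0027 without PRSS8 replicate 2 and 0.099 without PRSS8 replicate 1. Fatty acid synthesis had a median of −0.05 (adjusted p = 0.59), with FASN at −0.37 (SE 0.70) and THRSP at −0.18 (SE 0.18). Its median was −0.38 without control replicate 2, −0.25 without PRSS8 replicate 1, 0.11 without PRSS8 replicate 2 and 0.32 without control replicate 1. DNA replication genes had a median of 0.08 (adjusted p = 0.30), with CDC6 at 0.80 (SE 0.69) and CDC45 at 0.28 (SE 0.28). That median was −0.013 after quantile normalization, 0.0094 without control replicate 2 and 0.17 without control replicate 1. Replication-dependent histones had a median of 0.16 (adjusted p = 0.25), −0.06 in pair 1 and 0.27 in pair 2, with H1-2 at 0.75 (SE 0.96) and H2AC6 at 0.39 (SE 0.49). Leaving out an array moved this list both ways. Its median was 0.76 without PRSS8 replicate 1, 0.51 without control replicate 2 and −0.40 without PRSS8 replicate 2. These medians carry part of the difference between the replicate numbers. On the 4 arrays the list had an adjusted p = 0.89 in camera with an estimated correlation, which was 0.95. MYC targets in ribosome biogenesis had a median of 0.10 (adjusted p = 0.49), with RRP9 at 0.29 (SE 0.45) and NOP16 at 0.22 (SE 0.37), and a median of −0.25 without control replicate 2, −0.06 without PRSS8 replicate 1, −0.02 without PRSS8 replicate 2 and 0.12 without control replicate 1. Cytosolic ribosomal proteins had a median of 0.04 (adjusted p = 0.59), with RPL27 at 0.20 (SE 0.73) and RPS16 at 0.14 (SE 0.19).

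Outside the lists, EMP1, an epithelial membrane protein, differed by 1.77 (SE 1.05) and ERP44, a chaperone of the early secretory pathway, by 1.51 (SE 0.95). Arrays of the 2 numbers lay far apart within a group (SD 1.23 and 1.28 for EMP1, 1.19 and 0.55 for ERP44), while the differences in the pairs were 1.82 and 1.73 for EMP1 and 1.05 and 1.97 for ERP44. With the replicate block the SE was 0.24 for EMP1 and 0.33 for ERP44.

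Of the 10 largest negative differences among genes whose 4 array-to-array differences had one sign, 8 were of microRNA genes, 6 of them in the MIR548 family. Members of this family are related in sequence, though no sequences were compared here. A probe set may read a locus other than the gene it is named for, so single members are uncertain. MIR548AI stood at 13.71 ± 1.31 against 15.80 ± 0.07, a difference of −2.09 (SE 0.77), and MIR548AJ2 differed by −1.91 (SE 0.74). MIR548AD, MIR548G, MIR548A3 and MIR548H2 differed by −1.61 (SE 0.84), −1.45 (SE 0.88), −1.37 (SE 0.82) and −1.23 (SE 0.96). Outside that family MIR590 differed by −1.19 (SE 0.23) and MIR4652 by −1.15 (SE 0.71), the second with −0.11 in pair 1 and −2.19 in pair 2. ABCC2, an export pump for conjugated compounds, differed by −1.83 (SE 1.13), with −2.86 in pair 1 and −0.80 in pair 2. CYP24A1, the enzyme that inactivates vitamin D, differed by −1.41 (SE 0.90), with −2.24 in pair 1 and −0.58 in pair 2.

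Markers of other cell types lay low on all arrays. The 5 lists (fibroblast, leukocyte, endothelial, neuroendocrine and other epithelial lines) had median levels from 3.46 to 3.79 and median differences from −0.06 to 0.03, and the lowest camera adjusted p was 0.15, for fibroblast markers.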

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

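The tests of explanations in this part were all chosen after the result was seen, and the counts of probe sets without a gene name were planned only as one total over all transcript clusters.

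Probe sets that the comparisons by gene did not use were counted as well. Among the 42204 transcript clusters with no entry in the annotation, 35 stood at least 1.5-fold higher on both PRSS8 arrays than on both control arrays, and 42 at least 1.5-fold lower. Grouping each control array with the PRSS8 array of the other number gave 28 and 19, so the count of higher clusters was not far above that of a grouping without the PRSS8 contrast. Of the 1543 probe sets annotated with several gene symbols, 1 stood at least 1.5-fold higher on both PRSS8 arrays.

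The arrays grouped by replicate number: grouping them that way gave 7546 genes past the threshold in limma, where control against PRSS8 gave 0 genes (42 at an unadjusted p under 0.05). An exchange of control and overexpression arrays is argued against, since PRSS8 on the lower of the overexpression arrays stood 6.89 log2 above the higher control array. A difference in array handling may have contributed: the bacterial spike-ins, which measure no cell RNA, differed by at least 1.49 log2 between arrays of different numbers and by at most 0.28 within a number. Long genes were also read lower on the replicate 2 arrays, with Spearman's rho of −0.55 across 5786 genes (bootstrap 95% interval −0.57 to −0.53; genes are not independent replicates) between gene span and the change from number 1 to number 2, which is consistent with a difference in RNA integrity or labelling. No biological explanation was tested, because the labels give no difference between the replicate numbers.

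The second pattern is the upward shift of gene lists, weighed against a shift of all genes of similar level, since among genes with a mean of at least 6 the median difference was −0.02 in pair 1 and 0.22 in pair 2. For the unfolded protein response, integrated stress response and proteasome lists this is argued against as the whole cause: their medians lay at or above the 99.59th percentile of 10000 level-matched random lists in both pairs. For the oxidative phosphorylation, oxidative stress, mitotic, epithelial junction and hypoxia lists it cannot be told apart from a real shift, because 0 of the 5 lists lay above the central 95% of the random lists in both pairs, 4 did so in 1 pair and 1 in neither. The random lists were drawn gene by gene and matched on level only, not on gene span. Their percentiles overstate how rare a median is where list members move together. Camera estimated correlations of 0.12, 0.22 and 0.10 for the first 3 lists. The proteasome call was also lost after quantile normalization (camera, adjusted p = 0.20). PRSS8 expression stays open as a hypothesis for the first 3 lists. So does the load of any abundant secretory or membrane protein on the ER, since no other such protein was expressed as a control. The call of each of the 8 lists was also lost in camera with an estimated correlation (lowest adjusted p = 0.63). The size of the correlation alone does not account for this. For oxidative stress genes the estimate was 0.015, near the preset 0.01. That test rests on 2 residual degrees of freedom and has little power, so the lost calls do not decide whether the lists shifted.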

How the results depend on the processing

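Alternatives chosen after seeing the data were the set tests that combine the replicate block with an estimated correlation or fry, and the counts of genes 1.5-fold apart within both pairs; all others were fixed before. The count of 0 genes past the threshold held under every alternative on the 4 arrays (in limma without a block, 19 to 207 genes had an unadjusted p under 0.05), and PRSS8 kept its direction under all, at 7.13 to 7.86 when each array was left out in turn. Leaving out an array gave 0 to 5 genes higher, 0 to 59 lower, 0 to 60 changed at least 2-fold, 1 to 7 lists up and 0 to 1 down; 60 to 682 genes were then at least 1.5-fold higher and 63 to 421 lower, as fewer arrays have to stand apart. Of the reversed lists, the medians without PRSS8 replicate 1 were −0.15 (mitotic) and 0.0085 (hypoxia and glycolysis), and without control replicate 2 they were −0.09 (mitotic), 0.07 (hypoxia and glycolysis), 0.14 (epithelial junction) and 0.24 (proteasome), with camera's direction down although the median was above 0 in all but the mitotic list. Over the 4 arrays left out, the ranges were −0.15 to 1.29 (mitotic), 0.0085 to 0.24 (hypoxia and glycolysis), 0.043 to 0.34 (epithelial junction) and 0.24 to 0.55 (proteasome), as well as 0.37 to 0.92 (unfolded protein response), 0.25 to 0.56 (integrated stress response) and −0.08 to 0.36 (oxidative phosphorylation). All values and counts with an array left out also carry part of the difference between the replicate numbers, so they do not measure the stability of the PRSS8 difference alone. Genes at least 1.5-fold higher numbered 10 after quantile normalization, 28 after median centring and 52 with every transcript cluster counted; genes at least 1.5-fold lower numbered 5 with the mean of a gene's probe sets and 50 with every transcript cluster. At 1.2-fold the counts were 95 higher and 44 lower, and at 2-fold 7 and 2. Lists shifted up numbered 2 after quantile normalization, 3 after median centring, 3 after cyclic loess, and 0 with an estimated correlation and 0 with fry; 1 list, WNT/beta-catenin targets (median −0.13, adjusted p = 0.022), was shifted down when genes below the median level were left out. The cause of these moves was not tested, except that counting clusters adds unnamed ones and another fold size moves the limit.

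The labels do not say that equal replicate numbers mark a shared culture or day, but the arrays grouped by number. Arrays of one number deviated together from the group means (correlation 0.91 across genes), and the differences in the 2 pairs correlated at 0.17. With the replicate block, 0 genes passed, 1174 had an unadjusted p under 0.05 against 42 without it, and the lowest adjusted p was 0.076, for PRSS8. Of the lists, 9 were shifted up under the block (cholesterol synthesis was added, adjusted p = 0.017), 0 with the block and an estimated correlation, and 1 with the block and fry (mitotic genes, adjusted p = 0.0039). Within both pairs, the pairing gave 103 genes at least 1.5-fold higher and 35 lower. Adjusted over the list alone, 21 list members passed under the block, 15 of them in the unfolded protein response list. Of 1102 values of named genes under alternatives, 14 moved by more than the spread between replicates. Only the further normalizations and the mean of a gene's probe sets could give such a move. Leaving out an array cannot exceed that spread, and the other alternatives leave the difference unchanged, so the count says little about stability. Signal over background could not be computed, so what dim probe sets can show stays unknown.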

Other observations

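The tests in this part were all chosen after the result was seen, and so were the 6 gene lists in the next paragraph.

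The 6 lists cover further parts of the secretory pathway and the tRNA synthetases, and 5 of them passed camera with the preset correlation while none passed with an estimated one (adjusted p = 0.22 to 0.24). Genes of the 34 fixed lists were left out of these 6 lists, so HERPUD1, SEL1L, WARS1 and AARS1 are not in them. The values below describe the remaining genes and not the whole pathways. In limma 0 of the remaining members passed, and 0 had an unadjusted p under 0.05. The coat proteins of COPII and COPI vesicles had a median difference of 0.59 (camera, adjusted p = 2.9e-06 over the 6 lists; adjusted p = 0.22 with an estimated correlation), with 0.34 in pair 1 and 0.85 in pair 2, and 20 of 21 members were higher in both pairs. The list of the translocon and signal recognition had a median of 0.52 (adjusted p = 8.2e-05; adjusted p = 0.24 with an estimated correlation), with 0.23 in pair 1 and 0.75 in pair 2 and 15 of 21 members higher in both pairs. ER-associated degradation had a median of 0.36 (adjusted p = 1.3e-05; adjusted p = 0.22 with an estimated correlation; 0.13 in pair 1 and 0.52 in pair 2) and N-glycosylation 0.25 (adjusted p = 2.8e-04; adjusted p = 0.22 with an estimated correlation), with 0.46 in pair 2 but 0.05 in pair 1, at the 93.9th percentile of level-matched random lists and so inside their central 95%.

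Cytosolic tRNA synthetases, several of which are targets of ATF4, had a median of 0.46 (camera, adjusted p = 0.0014; adjusted p = 0.22 with an estimated correlation), with 0.18 in pair 1 and 0.77 in pair 2, and 12 of 16 were higher in both pairs. This list does not hold WARS1 and AARS1, which belong to the integrated stress response list. The mitochondrial synthetases had a median of 0.09 (adjusted p = 0.055), with 5 of 16 higher in both pairs. The hypothesis that the cytosolic enzymes and not the mitochondrial ones differ was set against level-matched random lists: the cytosolic list lay at the 98.97th percentile or above in both pairs, and the mitochondrial list at 63.5 and 87.9. The hypothesis stays open, because the mitochondrial list passed upward in one alternative (adjusted p = 0.035 with the replicate block; adjusted p = 0.59 with the block and an estimated correlation), and the 2 lists were not tested against each other.

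Probe sets of the MIR548 family and of RNU6 genes and pseudogenes were lower on the PRSS8 arrays, with medians of −0.42 (42 genes, bootstrap 95% interval −0.61 to −0.24) and −0.37 (79 genes, −0.58 to −0.24), lower in both pairs for 29 and 48 members. All intervals in this paragraph resample genes, which are not independent replicates, so they carry no spread between arrays. A lower recovery of all short RNAs may account for pair 1, where 127 snoRNA and scaRNA genes with a mean level of at least 6 had a median of −0.31 against −0.31 for MIR548 and −0.21 for RNU6, but is argued against for pair 2, where they had a median of 0.31 (0.14 to 0.40) against −0.38 and −0.50. Scaling between arrays is argued against, since after the 3 further normalizations the family median nearest to 0 was −0.34. Whether the probe sets of related copies share one signal cannot be told apart from separate changes in either family. The SD of the change was 0.36 over RNU6 members (interval 0.32 to 0.40). Over MIR548 members it was 0.75 (0.51 to 0.99), above the limit of 0.65 set for separate changes but with an interval that includes that limit. PRSS8 expression stays open as an untested biological explanation, and the arrays cannot separate mature microRNA from its precursor or host transcript.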
